A study of Oryza sativa with 12 samples.

How the data were processed

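Messenger RNA was profiled in spikelets of rice (Oryza sativa) from 2 cultivars, IRGA 428 and BR-IRGA 409, at 2 daytime temperatures, with 3 libraries in each of the 4 groups and 2 plants behind each library. Cultivar, temperature and replicate number were taken from the sample titles and characteristics in the labels. Per the labels' protocols, total RNA was extracted with a plant RNA reagent and libraries were made with an Illumina TruSeq RNA kit, and per the series' design text they were sequenced as single-end reads. The deposited values are raw read counts per gene, 1 file per library, not normalized and not pooled over replicates. Per the submitters' processing notes, the authors used Trimmomatic 0.33, HISAT2 2.05 and HTSeq 0.6.1, tools for read trimming, alignment and counting; their parameters, the genome build and the use of strand are not given in the sources used here. If strand was not used, reads of overlapping antisense genes cannot be told apart. Reads with several alignments stood in a line of their own and not in the gene counts, so values of genes with near-identical copies are uncertain.

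Each file listed 57174 genes and closed with 5 summary lines that name no gene. These lines were kept out of library sizes and tests. Reads outside any gene made up 6.04% to 10.3% of a library, reads that were not aligned 10.1% to 10.9%, reads with several alignments 3.70% to 5.34%, and ambiguous reads 0.0301% to 0.0326%; the low-quality line held 0 reads in each library. The remaining 75.0% to 80.2% were assigned to genes. Library sizes, as gene counts, ran from 7.08 to 75.4 M (M, 1000000 counts). The files give gene IDs that start with MH and do not pair them with names. Of the 57174 IDs, 0 matched the reference table of rice genes used here, so genes appear under their IDs. The digits after MH in an ID are read here as a chromosome number, which the files do not state, and no coordinates are given.

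Gene counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with the filterByExpr function, which left 22321 genes, and libraries were scaled by trimmed mean of M-values. A negative binomial model with 1 mean per group was fitted to all 12 libraries, so that the groups shared an estimate of the spread with 8 residual degrees of freedom. Contrasts were tested with the robust quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method within each contrast. A gene was called when its adjusted p was below 0.05. The 5 contrasts were 38 °C against 29 °C in each cultivar, the difference between these responses (the interaction), and BR-IRGA 409 against IRGA 428 at each temperature. Fold changes are on the log2 scale with their standard errors (SE), and levels are CPM, counts per 1000000 on the scaled library sizes, given as mean ± SD over 3 libraries. These contrasts, the threshold and the rule for naming genes were set before the data were examined.

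By that rule, at most 2 higher and 2 lower IDs were named per contrast when no names could be had: those with the largest fold change among called genes with a mean log2 CPM of at least 1 over the 12 libraries and no overlap between the CPM values of the groups compared (no such condition for the interaction). Tests of gene lists by function had been planned and were not run, because the lists are defined by gene names. For a gene with 0 counts in a whole group, the fold is a lower bound, computed with 3 counts over that group. For a gene with 1 to 3 counts there, it is a ratio of summed counts with an exact Clopper-Pearson 95% interval. Bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Measures of single libraries were compared by exact two-sided permutation tests, in which 3 libraries against 3 cannot give a p below 0.1.

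The model was tested on simulated counts drawn from the means and library sizes of these libraries, with known changes in about 200 genes. Of genes changed by 1 on the log2 scale, 42.4% were recovered for heat in IRGA 428, 30.6% for heat in BR-IRGA 409, 4% for the interaction, 32% for the cultivars at 29 °C and 41.4% at 38 °C. For a change of 2 the shares were 84%, 78%, 57.6%, 77% and 79%, in the same order. Between 1 and 7 unchanged genes were called per contrast, with 22052 to 22065 genes tested. These shares hold for few changed genes and a spread taken as equal in all groups. With more changed genes the adjusted threshold is less strict, so the shares do not measure the power of the real contrasts.

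Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), other scalings (relative log expression and upper quartile), no filter, a filter of 1 CPM in 3 libraries, stricter thresholds, fits of only the groups compared, and leaving out each library. Added after the data had been seen were random thinning of all libraries to the size of the smallest, and a fit without a close pair of IRGA 428 libraries. Counts of genes were also obtained for the other ways of dividing the same libraries into groups of 3. No library was left out of the main analysis. DESeq2 was fitted to all 57174 listed genes with its own filter, so its counts differ from those of edgeR in gene set as well as test. The labels do not say what a replicate number marks. At 29 °C, deviations from the group means correlated between the cultivars by 0.18 to 0.314 in the 3 pairs of equal number and by −0.207 to −0.073 in the others. This pair of groups was picked because its numbers matched, so the match may be due to chance. Library 1 was also the shallowest and library 2 the deepest at 29 °C in both cultivars. This check by pair of groups, and the fits with the number as a block at 29 °C alone, were added after the calls had been seen.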

Results

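Spikelets from the mid-panicle were sampled at anthesis, the stage of flower opening and pollination, from the rice cultivars IRGA 428, described in the labels as heat sensitive, and BR-IRGA 409, described as heat tolerant. Plants were kept at 29 °C (control) or 38 °C (heat) for 7 h of the day on 3 days, and spikelets were frozen at the end of the treatment. Each of the 4 combinations was represented by 3 libraries, each made from 2 plants. Mean sequencing depth, as gene counts per library, was 13.7 ± 4.18 M (M, 1000000 counts; SD, n = 3) for IRGA 428 at 29 °C and 21.4 ± 5.27 M at 38 °C. For BR-IRGA 409 it was 10.0 ± 4.29 M at 29 °C and 53.4 ± 19.4 M at 38 °C. Depth and temperature were thus linked in both cultivars. All 3 heat libraries were deeper than all 3 control libraries, by 5.32 times in the mean in BR-IRGA 409 and by 1.56 times in IRGA 428 (exact permutation p = 0.1 in each, the smallest possible with n = 3).

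The largest axis of variation among the libraries separated the cultivars. The deposited files of BR-IRGA 409 carry the word new in their names, and its meaning is not known here. Whether the cultivars were sequenced in separate runs is therefore open, and such a difference could not be told apart from cultivar. The first principal component of log2 CPM over 22321 genes held 42.5% of the variance and placed the 6 IRGA 428 libraries between −98.9 and −44.0 and the 6 BR-IRGA 409 libraries between 34.4 and 89.1. Temperature also went along this axis: in BR-IRGA 409 control libraries lay at 34.4 to 46.0 and heat libraries at 70.2 to 89.1. In IRGA 428 heat libraries also lay above controls, but control 2 and heat 1 were close (−56.46 and −56.05). The second component (29.6%) separated the temperatures in BR-IRGA 409, with control libraries at 52.5 to 81.3 and heat libraries at −50.0 to −16.4, whereas in IRGA 428 control 2 and heat 1 nearly coincided (−14.0 and −14.3). In IRGA 428, the libraries of control 3 and heat 1 lay together on the third component (10.2%), at −59.6 and −53.8, while control 2 lay at 52.8. These libraries of different temperature had a biological coefficient of variation of 0.0791 between them, below the range of 0.115 to 0.368 among pairs of the same group in this cultivar. In BR-IRGA 409, the coefficient was 0.119 to 0.241 within a group and 0.287 to 0.434 between temperatures.

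**Figure D1:**
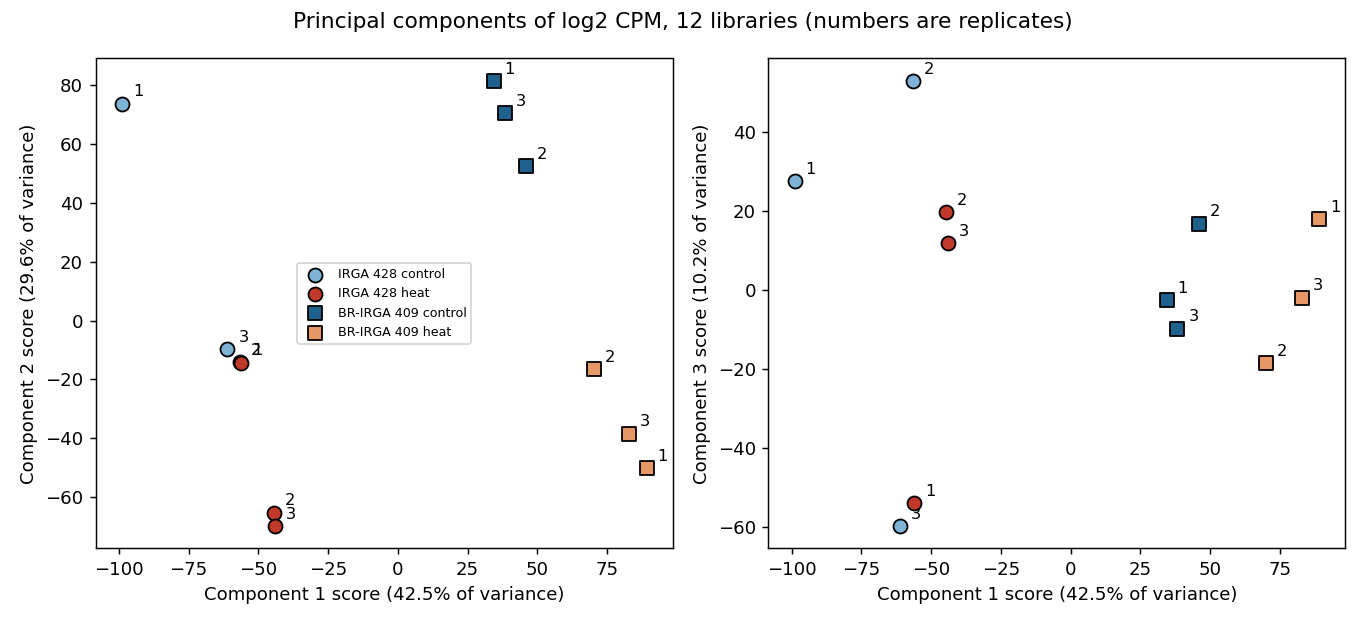
Scores of the 12 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM; each point is a library, colour and shape give cultivar and temperature, and numbers are replicates. The cultivars separate on component 1, and in IRGA 428 control 3 lies beside heat 1 on component 3 (−59.6 and −53.8).

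The first question was how the spikelet transcriptome of the tolerant cultivar changed at 38 °C. In BR-IRGA 409, 2646 of 22321 genes (11.9%) were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1501 higher and 1145 lower in heat. Genes that rose did so by a median log2 fold change of 1.198 and genes that fell by a median of −0.849. At least a 2-fold change was found for 1344 genes, 877 higher and 467 lower. Rises over 4-fold (389 genes) outnumbered falls over 4-fold (121 genes), and 74 genes rose over 10-fold. A minority of the changes concerned transcripts of low abundance. Of the 1501 higher genes, 240 rose from a mean below 1 CPM at 29 °C, of which 3 reached 10 CPM or more. Of the 1145 lower genes, 148 fell to below 1 CPM at 38 °C.

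Among called genes with a mean log2 CPM of at least 1 whose heat and control libraries did not overlap (1249 higher, 996 lower), MH02g0593700 had the largest rise, from 0.128 ± 0.126 CPM (SD, n = 3) at 29 °C to 62.1 ± 60.3 CPM at 38 °C (log2 fold change 8.82, SE 2.51, edgeR adjusted p = 0.0457). MH05g0404300 rose from 0.667 ± 0.261 to 24.2 ± 22.8 CPM (log2 fold change 5.23, SE 1.36, edgeR adjusted p = 0.0373). The largest falls were those of MH08g0334900, from 7.73 ± 5.24 to 0.389 ± 0.133 CPM (log2 fold change −4.28, SE 0.91, edgeR adjusted p = 0.0236), and MH10g0437100, from 5.79 ± 3.64 to 0.538 ± 0.226 CPM (log2 fold change −3.42, SE 0.61, edgeR adjusted p = 0.0179). The level of MH02g0593700 differed widely between the heat libraries, with 4497, 185 and 4057 counts. The calls of the 4 genes, in this order, held in 8, 9, 9 and 11 of 16 alternative settings, left-out libraries included. In IRGA 428 these 4 genes had log2 fold changes of the same sign, 1.78, 1.95, −1.92 and −1.27, and edgeR adjusted p-values of 0.6, 0.469, 0.403 and 0.411. For each of the 4 genes, the heat and control libraries of IRGA 428 overlapped in CPM. MH02g0593700 had 13.5 CPM (233 counts) in control 2 and 0.427 CPM (7 counts) in heat 1.

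**Figure D2:**
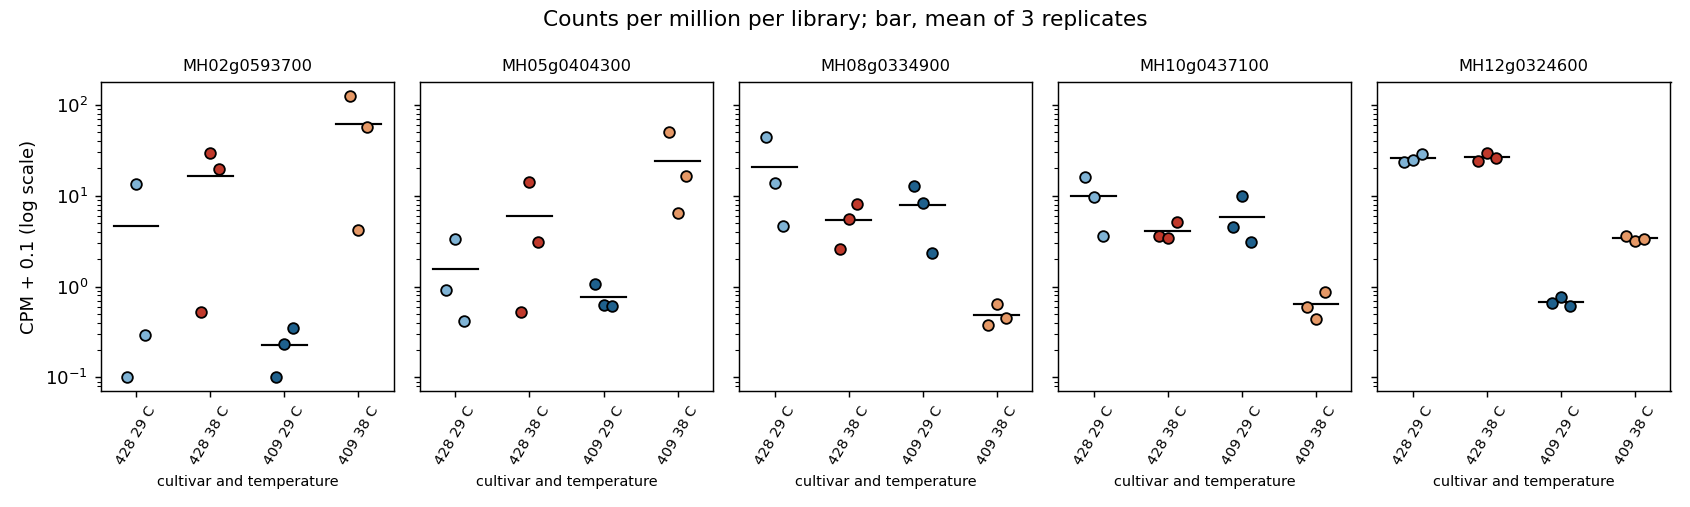
CPM, library-size scaled counts (log axis, 0.1 added) of 5 genes in each of the 12 libraries, by cultivar (428, IRGA 428; 409, BR-IRGA 409) and temperature; points are libraries and bars are means of 3 replicates. In BR-IRGA 409 the mean of MH02g0593700 went from 0.128 to 62.1 CPM, and MH12g0324600 stayed near 26 CPM in IRGA 428 and went from 0.573 to 3.29 CPM in BR-IRGA 409.

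The number of calls in BR-IRGA 409 depended on each library. It was 47, 153 and 18 without control 1, 2 and 3, and 66, 1702 and 41 without heat 1, 2 and 3. DESeq2, fitted to all 57174 listed genes, called 4675. A fit of only these 6 libraries called 5001, a fit without the filter on low counts called 1596, and an edgeR adjusted p below 0.01 left 51. The excess of higher genes did not hold with limma-voom (1053 higher, 1131 lower) and was small with upper-quartile scaling (1318 and 1295).

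The same comparison in the sensitive cultivar gave 0 called genes with edgeR (smallest adjusted p = 0.401). At an unadjusted p below 0.05 there were 2614 genes (11.7%), limma-voom also called 0 genes, and DESeq2 called 13. The count of 0 rested on a single library: without control 3, which lay close to heat 1, edgeR called 1518 genes, 771 higher and 747 lower. Without both control 3 and heat 1 it called 1238.

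Genes called in BR-IRGA 409 mostly had fold changes of the same sign in IRGA 428, where none of them passed. Of the 1501 genes higher at 38 °C in BR-IRGA 409, 1438 (95.8%) had a positive fold change in IRGA 428, with a median log2 value of 0.466 against 1.198. Of the 1145 lower genes, 1057 (92.3%) had a negative one, with a median of −0.334 against −0.849. Over all genes tested, 75.5% had the same sign in both cultivars. The medians in BR-IRGA 409 are of genes selected there, which enlarges them. Among the 389 genes that rose over 4-fold in BR-IRGA 409, 379 had a positive fold change in IRGA 428. At an unadjusted p below 0.05 in IRGA 428, 865 of the 2646 genes had the same sign and 6 the opposite one; adjusted over the list alone, 0 passed (edgeR, smallest adjusted p = 0.11), and 0 genes were called in both cultivars, or 866 without IRGA 428 control 3. Across all 22321 genes, the log2 fold changes correlated with Pearson's r = 0.687 and Spearman's rho = 0.677, a description across genes, which are not independent replicates. Without the filter on low counts r was 0.278. The responses shared no libraries, but they shared the estimates of the spread. In both cultivars all heat libraries were deeper than all control libraries. Agreement in sign may therefore reflect temperature or a property that goes with depth, which cannot be told apart here.

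**Figure D3:**
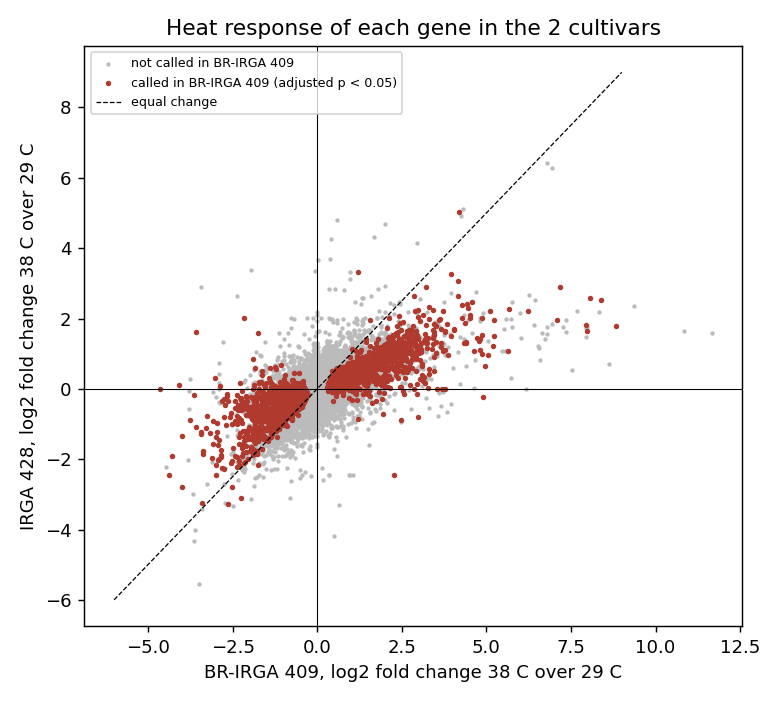
Log2 fold change at 38 °C over 29 °C of each of 22321 genes in BR-IRGA 409 (horizontal) and IRGA 428 (vertical); red points are the 2646 genes called in BR-IRGA 409 and the dashed line marks equal change. Red points lie mainly in the quadrants of equal sign, 1438 of 1501 higher genes and 1057 of 1145 lower genes.

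To place each IRGA 428 library on this response, a score was formed as the mean log2 CPM of the 1501 higher genes minus that of the 1145 lower genes, each gene centred on the 6 IRGA 428 libraries. It was −1.34, −0.249 and −0.0773 in the control libraries and 0.126, 0.709 and 0.831 in the heat libraries. The means were −0.556 ± 0.685 (SD, n = 3) and 0.556 ± 0.377, without overlap between temperatures (exact permutation p = 0.1, two-sided, the smallest possible). The score also followed depth, with Pearson's r = 0.973 (exact permutation p = 0.00417) and Spearman's rho = 0.943 (exact permutation p = 0.0167) against log2 gene counts over the 6 libraries, and r = 0.932 without the deepest and the shallowest. With score and depth each centred on the mean of their temperature, r was 0.959 (exact permutation p = 0.0556).

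Whether the cultivars responded differently to heat was tested by the interaction, and 1 gene passed. MH12g0324600 had 25.8 ± 2.83 CPM (SD, n = 3) at 29 °C and 26.6 ± 2.91 CPM at 38 °C in IRGA 428, against 0.573 ± 0.0799 and 3.29 ± 0.243 CPM in BR-IRGA 409. Its log2 fold change in heat was larger in BR-IRGA 409 by 2.43 (SE 0.23, edgeR adjusted p = 0.00955). The level in BR-IRGA 409 at 29 °C rested on 4, 10 and 4 counts, so this difference is less certain than the SE and adjusted p imply. An unadjusted p below 0.05 was reached by 1236 genes (5.54%), close to the share that chance gives. The count of called genes was 0 with limma-voom, 42 with DESeq2, 2 without IRGA 428 control 1, and 0 without any 1 of IRGA 428 heat 3 and BR-IRGA 409 control 1, 2 or 3. It was also 0 with the replicate number as a block among the 29 °C libraries, where equal numbers correlated (MH12g0324600, edgeR adjusted p = 0.0549). For the rest of the genes, the larger number of calls in BR-IRGA 409 was therefore not matched by a detected difference between the responses. In the simulation with few changed genes, the interaction test recovered 4% of changes of 1 on the log2 scale, so the lack of calls does not show that the responses were equal.

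The remaining comparisons asked how the cultivars differed at each temperature. At 29 °C, 903 genes were called by edgeR (Benjamini-Hochberg adjustment), 423 higher in BR-IRGA 409 and 480 higher in IRGA 428. Their median log2 differences were 1.97 and −2.35, and 710 differed by at least 2-fold. MH02g0485000 had 204 ± 58.1 CPM (SD, n = 3) in BR-IRGA 409 and 0 counts in IRGA 428, at least 2779-fold higher, and MH11g0656100 had 68.7 ± 21.1 CPM and 0 counts, at least 1050-fold higher. In the other direction, MH03g0754400 had 57.7 ± 11.6 CPM in IRGA 428 and 0 counts in BR-IRGA 409, at least 565-fold higher, and MH02g0335900 had 57.5 ± 23.5 CPM and 0 counts, at least 581-fold higher. Their edgeR adjusted p-values were 2.94e-05, 4.11e-05, 1.01e-06 and 1.71e-05. A fit of only these 6 libraries called 474 genes, or 370 with the replicate number as a block, and 514 had an adjusted p below 0.01.

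At 38 °C, 1458 genes were called by edgeR, 693 higher in BR-IRGA 409 and 765 higher in IRGA 428, with median log2 differences of 1.61 and −1.73. MH11g0656100 again had 0 counts in IRGA 428 and 38.3 ± 6.77 CPM in BR-IRGA 409, at least 784-fold higher. MH11g0655200 had 49.7 ± 3.50 CPM in BR-IRGA 409 and 1 count in all in IRGA 428, a ratio of 3178 (95% interval 570 to 125500). MH01g0579300 had 51.7 ± 4.75 CPM in IRGA 428 and 0 counts in BR-IRGA 409, at least 2635-fold higher, and MH02g0310200 had 78.7 ± 18.4 CPM against 2 counts in all, a ratio of 6098 (95% interval 1687 to 50370). Their edgeR adjusted p-values were 3.05e-05, 3.68e-07, 5.69e-07 and 5.52e-08. The heat libraries of BR-IRGA 409 were the deepest; with all libraries thinned to the smallest, 956 genes were called, and without BR-IRGA 409 heat 3 there were 926. DESeq2 called 2488 genes, and 843 had an edgeR adjusted p below 0.01.

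Most of the cultivar differences called at 29 °C were also called at 38 °C, where the list was longer. Of the 903 genes called at 29 °C, 751 were among the 1458 called at 38 °C, and 750 of them in the same direction (83.1% of the 903). Of these, 330 were higher in BR-IRGA 409 and 420 in IRGA 428, where independent lists would share 13.1 and 16.5. Of the 751, 605 differed by at least 2-fold at both temperatures in the same direction. The libraries of the comparisons were separate, but both contrasts used the same estimates of the spread, so the lists were not fully independent. Across all genes, the log2 differences at 29 °C and 38 °C had a Pearson's r of 0.859 and a Spearman's rho of 0.399, again a description across genes.

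The 750 genes were unevenly spread over the chromosome numbers read from the IDs, a comparison chosen after the calls had been counted. On chromosome 12, 134 of 1209 tested genes (11.1%) belonged to the set, against 2.92% elsewhere (odds ratio 4.15, 95% interval 3.38 to 5.06, Fisher's exact test, adjusted p = 2.22e-34 over 12 chromosomes). Chromosome 11 (6.13%, adjusted p = 4.51e-07), chromosome 10 (5.03%, adjusted p = 0.00262) and chromosome 4 (4.804%, adjusted p = 0.000915) also held more. Chromosome 7 held 12 of 1719 genes (0.698%, adjusted p = 3.35e-13), and chromosomes 5, 3, 6 and 1 held 1.37%, 1.82%, 1.91% and 2.65% (adjusted p = 1.92e-07, 4.17e-07, 0.000288 and 0.022). With genes of 3 counts or fewer in a cultivar taken out of the set but kept among the tested genes, the share on chromosome 12 was 7.36% against 2.18% elsewhere. The test treats genes as independent, which neighbours are not. The 2646 genes called between the temperatures in BR-IRGA 409 showed no such difference for any of the 12 chromosomes (Fisher's exact test, smallest adjusted p = 0.65).

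**Figure D4:**
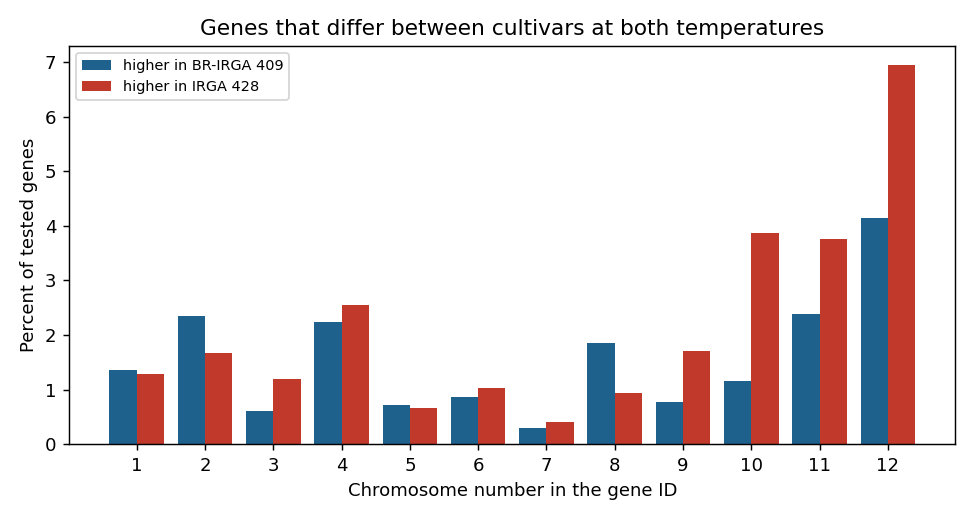
Percent of tested genes on each chromosome, as read from the gene IDs, that were called between the cultivars at both temperatures in the same direction; blue bars are genes higher in BR-IRGA 409 and red bars genes higher in IRGA 428. The bars are tallest on chromosome 12, at 4.14% and 6.95%, and lowest on chromosome 7, at 0.291% and 0.407%.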

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

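The following tests were set before their results were seen, except the comparison of reads with several alignments, chosen after the library totals had been read. The division of the regroupings by the groups of BR-IRGA 409 and 3 of the alternatives (equal depth, the block at 29 °C, and the fit without IRGA 428 control 3 and heat 1) were also chosen after results were seen. The interaction test singled out MH12g0324600, whose log2 heat response was larger by 2.43 in BR-IRGA 409 than in IRGA 428. Its level in IRGA 428 exceeded that in BR-IRGA 409 at both temperatures, with log2 differences of −5.45 at 29 °C and −3.02 at 38 °C for BR-IRGA 409 over IRGA 428. The gene stayed past the threshold in 14 of 23 alternatives, with log2 values of 2.25 to 2.56 and adjusted p-values of 1.06e-05 to 0.521. Of 60 regroupings of the libraries within cultivars, 6 gave as many called genes as the real grouping, which gave 1, with itself among the 6; the highest of the others also gave 1. All 6 kept the labelled groups of BR-IRGA 409, where this gene changed, and the 54 that altered them gave 0, so the count of these splits says nothing about chance, and the 10 splits of BR-IRGA 409 are too few for a share under 0.05.

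Outside the gene counts, reads with several alignments took 5.15% ± 0.173 (SD, n = 3) of the BR-IRGA 409 libraries at 38 °C and 3.76% ± 0.0585 at 29 °C, a difference of 1.39 percentage points with all heat libraries above all control libraries (exact permutation p = 0.1, the smallest possible). In IRGA 428 the shares of reads with several alignments were 4.55% ± 0.393 at 38 °C and 4.25% ± 0.157 at 29 °C (exact permutation p = 0.3). Its deepest library had the highest share (4.90%) and its shallowest the lowest (4.08%). Whether the change with temperature differed between the cultivars was not tested.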

How the results depend on the processing

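Chosen after the results were seen were the equal-depth fits, the blocks at 29 °C alone, the fit without IRGA 428 control 3 and heat 1, the alternatives to the correlation, and those for genes in 1 cultivar only and for chromosome 12. Counts of called genes are given in the order heat in IRGA 428 (0), heat in BR-IRGA 409 (2646), interaction (1), cultivars at 29 °C (903) and at 38 °C (1458), and 0 were shared between the heat responses. DESeq2, fitted to all 57174 listed genes, gave 13, 4675, 42, 1320 and 2488, with 11 shared. Limma-voom gave 0 for the interaction. Without a filter heat in BR-IRGA 409 gave 1596, and a change of at least 2-fold was met by 1344. An adjusted p below 0.01 left 51 for heat in BR-IRGA 409, 514 at 29 °C and 843 at 38 °C. Fits of only the groups compared gave 5001 for heat in BR-IRGA 409 and 474 at 29 °C. Thinning gave 956 at 38 °C. Without IRGA 428 control 3 and heat 1, heat in that cultivar gave 1238 and the interaction 0. Fewer genes pass a stricter threshold by construction; for the other changes the cause was not tested.

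Leaving out 1 library at a time, which leaves fewer samples, gave 0 to 1518 (the 1518 without control 3) for heat in IRGA 428 and 18 to 1702 for heat in BR-IRGA 409, where each of the 6 libraries moved the count by over 1.5 times. It gave 0 to 2 for the interaction, 623 to 1010 at 29 °C, 926 to 1339 at 38 °C (926 without BR-IRGA 409 heat 3) and 0 to 866 shared heat genes (866 without IRGA 428 control 3). The correlation of the responses ran from 0.57 to 0.703, and was 0.278 without a filter, where genes with few counts enter. Of the 13 named results, 187 alternatives kept the call, 36 lost it and 0 reversed. The 8 cultivar results kept it in each alternative (18 of 18 at 29 °C, 16 of 16 at 38 °C), and the heat genes of BR-IRGA 409 in 8 (MH02g0593700, adjusted p up to 0.33), 9 (MH05g0404300, 0.15), 9 (MH08g0334900, 0.0871) and 11 (MH10g0437100, 0.0648) of 16.

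Over all groups the replicate numbers did not pair the samples consistently. In the 18 pairs of equal number, deviations from the group means correlated by −0.409 to 0.577, 9 of them above 0.1. Of 12 libraries, 7 correlated best with their own number. With the replicate block at 29 °C alone, the interaction gave 0 and the cultivars at 29 °C gave 904, or 370 in a fit of only these groups, and the 4 genes named at 29 °C kept their calls. With the number as a replicate block over all groups, the counts were 0, 2638, 0, 789 and 1301, and with a replicate block within cultivar the interaction again gave 0 (MH12g0324600, adjusted p = 0.0877 and 0.521); the blocks moved no other count by over 1.5 times. Genes in 1 cultivar only numbered 42 for BR-IRGA 409 with up to 3 counts allowed in the other, and 25 for IRGA 428 and 10 for BR-IRGA 409 at 5 CPM. The share of chromosome 12 stayed above that elsewhere in 5 of 5 alternatives. Other scalings moved the share of higher genes by under 10 percentage points in each comparison. The cultivar with more higher genes was the other one at 29 °C with limma-voom (436 in BR-IRGA 409, 415 in IRGA 428) or without IRGA 428 control 3 (533 and 477; 607 and 477 without heat 1 also), and at 38 °C with DESeq2 (1248 and 1240) or only the groups compared (873 and 851). In the simulation with few changed genes, changes of 1 on the log2 scale were mostly missed (30.6% recovered for heat in BR-IRGA 409, 4% for the interaction). These shares do not measure the power of the real contrasts. Tests of gene lists were not run, since no names were matched.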

Other observations

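Chosen after the results were seen were the tests of doubled libraries and of depth among the IRGA 428 libraries, both tests of genes with counts in 1 cultivar only, the equal-depth fits and the windows along the ID order; the tests of neighbours, of exchanged labels and of other splits were set before. Genes that differed between the cultivars at both temperatures often stood side by side when the tested genes were ordered by ID. Neighbours here are successive tested genes, and IDs that were not tested were skipped. Among the 750 genes there were 208 neighbouring pairs, against a median of 37 and a maximum of 63 in 10000 shuffles within chromosomes (permutation p = 1e-04, the smallest these shuffles can give). Taken by direction, pairs were 8.29 times the shuffled median for genes higher in BR-IRGA 409 and 7.77 times for genes higher in IRGA 428. The longest run was 8 genes. In windows of 100 successive tested genes, the densest held 37 of the set on chromosome 11, 33 on chromosome 12, 31 on chromosome 4 and 29 on chromosome 10. A hypothesis is that these stretches may mark segments where the cultivars differ in descent; the 208 pairs fit it, and no sequence was compared. The 2646 heat genes of BR-IRGA 409 formed 345 pairs against a shuffled median of 313 and maximum of 375 (permutation p = 0.02), which lies above the median but within the range of the shuffles and leaves grouping by position undecided.

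With at least 1 CPM in each of the 6 libraries of a cultivar and 0 counts in the 6 of the other, 59 genes had counts in IRGA 428 only and 27 in BR-IRGA 409 only, a ratio of 2.19 (exact binomial p = 0.000732, which treats genes as independent). A count of 0 allows a level of up to 0.0285 CPM in IRGA 428 and 0.0158 CPM in BR-IRGA 409. Unequal depth does not account for the excess: BR-IRGA 409 had more counts in all (190 M against 105 M), which makes 0 counts there the stricter condition, and the ratio was 2.47 (74 and 30 genes) with all libraries thinned to the smallest. Poorer alignment of BR-IRGA 409 reads to the reference used remains open: the share of reads that were not aligned was 10.4% ± 0.278 (SD, n = 6) against 10.3% ± 0.110, a difference of 0.133 percentage points that lies within the spread between libraries (exact permutation p = 0.335). Genes absent from, or silent in, a cultivar are a biological possibility that was not tested.

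In IRGA 428, the libraries were also divided into control 1, control 3 and heat 1 against control 2, heat 2 and heat 3. This split gave 597 called genes, where the labelled groups gave 0. The 10 splits are too few for a share under 0.05, so the count does not establish another structure of the samples. Coefficients of variation went with this division only in part. Control 3 lay nearest heat 1 (0.0791) and control 2 nearest heat 2 (0.215). Control 1, however, lay nearer control 2 (0.331) than control 3 (0.368) or heat 1 (0.376). Control 3 and heat 1 were not copies of 1 library, since their counts differed with a mean chi-square of 5.91 per gene, where sampling noise gives about 1. Depth stays open: control 2 lay 3.88 times as far from heat 1 as control 3 did in coefficient of variation at nearly the same depth (16.4, 16.5 and 15.8 M), but the other libraries of the sides differed in depth (8.88 against 20.7 and 27.0 M). An exchange of the labels of control 2 and heat 1 could not be settled. The labelled split correlated with the BR-IRGA 409 heat response at r = 0.729, the highest of the 10 splits (on group means of log2 CPM, where the fitted fold changes gave 0.687), a split exchanging control 3 and heat 1 at 0.704, and the one exchanging control 2 and heat 1 at 0.561, the last with a difference of −0.168 from the labelled one that was negative with each of the 12 libraries left out; its jackknife SD of 0.237 is larger, so the bound set beforehand on the spread of a single correlation (0.143) was too narrow, and shared handling or plants of different stage stay open, untested.

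The heat calls of BR-IRGA 409 came with heat libraries 5.32 times as deep as the controls. Counting depth alone does not account for most of them: with all libraries thinned to equal size, 1810 genes were called, of which 1650 were shared with the full-depth calls. Of the 2646 genes called at full depth, 2514 still passed the filter. Their median absolute log2 fold change was 1.01 times that at full depth, and all 2514 kept their sign. Thinning keeps the expected ratio of a gene, so the fold changes and signs could hardly differ and say nothing about depth. A property that goes with depth, such as RNA input or quality, may still contribute, because the heat score of the IRGA 428 libraries also went with depth at equal temperature (r = 0.959 with both measures centred on their temperature), a relation that missed 0.05 (exact permutation p = 0.0556, smallest possible 0.0278). The score hardly changed on thinned counts, with −1.23 to −0.0762 in control libraries and 0.108 to 0.780 in heat libraries, which also follows largely from how thinning works. Temperature, the biological difference in the design, and such a property cannot be told apart here, as depth and temperature rise together.

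For the other comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The labelled split gave 2646 genes for heat in BR-IRGA 409, 903 for the cultivars at 29 °C and 1458 at 38 °C, and the highest of the other splits gave 0, 3 and 0.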
